A study of Mus musculus with 10 samples.

How the data were processed

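The study measured messenger RNA in cells sorted from the hippocampus of adult mice that carry 1 copy of a Sox1-GFP reporter, in which green fluorescent protein (GFP) is made where the Sox1 gene is active. Sox1 is a transcription factor of neural stem and progenitor cells. Per the labels, each hippocampus was dissociated with papain, and cells with high GFP or with no GFP were collected by flow cytometry. RNA was isolated, amplified with a kit named for fixed tissue (FFPE), and hybridised to Affymetrix Mouse Gene 1.0 ST arrays. Per the series description, the submitters left out 1 array of a young mouse whose fold changes against its replicates were skewed, and which array this was is not given in the sources used here.

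The deposited table holds log2 expression values, 1 column per array, that the authors obtained by Robust Multichip Average (RMA), per the submitters' processing notes. RMA subtracts background, sets the probe intensities of all arrays to the same distribution and summarises the probes of each probe set. Per the series description the probes were regrouped by RefSeq transcript of the mm9 genome build, and the version of RMA is not given in the sources used here. A quantile step removes any difference between arrays in total signal, and summarised log2 values understate changes of dim genes. The table gives no detection call or background level, so a low value cannot be told from no expression, and the number of arrays limits the precision.

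Samples were grouped by sort fraction and age from their titles. There were 4 GFP-positive samples of old mice (1 year 9 months), 3 GFP-positive samples of young mice (7, 5 and 4 months for replicates 1, 2 and 3) and 3 GFP-negative samples of young mice (7, 7 and 4 months). The series description gives the young mice as 5 to 7 months old, while the titles of 1 sample in each young group say 4 months. The titles were followed. No GFP-negative sample of old mice was analysed here, so age and sort fraction could not be tested together. The titles call the samples biological replicates. Young fractions with number 2 came from mice of different ages by title. For young fractions with numbers 1 and 3 the titles do not say whether they came from the same mouse.

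The table has 31672 probe sets named by RefSeq accession. Of these, 24590 matched 1 gene symbol in a RefSeq gene table of the assembly GRCm38.p6, 0 matched several and 7082 matched none, 6483 of them predicted transcripts. That table was used for names only, and no coordinates are given because its build differs from mm9. Probe sets without a symbol stayed out of the gene tests. The brightest probe set over all 10 samples stood for each of the 3010 genes with several, which left 19965 genes. In 11 groups, 27 genes in all, different genes had identical values on every array, so that such genes, Rps27 among those named, cannot be told from their near-identical copies. The same caution holds for the adult beta-globin genes.

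Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in 1 fit of 3 group means over all 10 samples, with 7 residual and 4.07 prior degrees of freedom, two-sided, and adjusted by Benjamini-Hochberg over all genes. An adjusted p under 0.05 counted as past the test. SE denotes the moderated standard error of a log2 difference. The submitters' text names Significance Analysis of Microarrays (SAM), which was not installed, so a permutation test of the same type, written for this work, was run as an alternative. The 24 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and the members were also tested adjusted over the list alone. As alternatives, camera was run with a correlation estimated for each list, and fry, which asks whether a list's genes move one way on balance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

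The lists covered cell types (neural stem and progenitor, astrocyte, immature and mature neuron, oligodendrocyte precursor, mature oligodendrocyte, microglia, a list of T cells, granulocytes and blood monocytes, endothelial, mural and fibroblast, ependymal and choroid plexus, and erythroid) and processes (cell cycle, cell cycle inhibitors and senescence, interferon response, antigen presentation, reactive glia and complement, Notch pathway, Wnt and BMP response, immediate early and dissociation response, hippocampal growth factors and receptors, cholesterol synthesis, ribosomal proteins, and oxidative phosphorylation). Some genes stand in more than 1 list, such as Egfr, Fgfr3, Notch1, Hes1, Hes5 and Btg2. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The rule named Sox1, Sox2, Nes, Gfap, Dcx and Mki67 always. It added the 6 largest changes in each direction among genes past the test whose groups did not overlap, or the 3 with the smallest p where none passed. From each list with a call or a member past the test it named the 3 members with the smallest p, and from any other list 1 member. A few genes that this rule names are not reported here.

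The tests were checked on simulated arrays with the means and spread of the real genes, 19965 genes of which 200 were changed. For GFP-positive against GFP-negative samples, 64 of 100 genes changed by a log2 value of 1 and 99 of 100 changed by 2 were recovered with 3 false calls. For old against young samples, the recovered numbers were 70 and 97 of 100 with 7 false calls. No list was called in either simulation (0 lists by camera). The simulated genes varied independently, unlike real genes.

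The alternatives left out the dimmest 33.3% or 50% of genes, fitted only the 2 groups compared, normalized the arrays again by quantiles or by their medians, averaged the probe sets of a gene or tested all probe sets, changed the variance model or weighted the arrays, and set the replicate number as a block. Others left out the mice of 4 months, took age in months as a covariate among young samples, or left out each sample in turn. Settings that left out samples with high choroid plexus genes or high Xist were added after these values were seen.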

Results

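Expression was measured on 10 arrays: 4 of GFP-positive cells from old mice, 3 of GFP-positive cells from young mice and 3 of GFP-negative cells from young mice. The array medians lay between 6.54 and 6.66 (log2 RMA value), and the SD over genes between 1.62 and 1.86. Arrays of the same group correlated across genes with r from 0.967 to 0.986, young GFP-positive and GFP-negative arrays with r from 0.906 to 0.940, and old and young GFP-positive arrays with r from 0.962 to 0.984. The first principal component held 63.3% of the variance and separated the GFP-negative samples, between 56.8 and 72.7, from the 7 GFP-positive samples, between -35.4 and -11.7. The second held 8.59%. In 1 old sample, replicate 3, Xist, the RNA that silences an X chromosome in females, had a value of 11.90, and the Y-linked gene Ddx3y had 5.32. In the other 9 samples Xist lay between 4.95 and 5.69 and Ddx3y between 9.15 and 9.83. These genes were looked at after the values had been seen, and the labels give no sex. By these values old replicate 3 had the pattern of a female and the other 9 samples that of males. Sex was thus not balanced between the old and the young samples.

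The sort comparison asked which genes set Sox1-GFP-positive cells of the young hippocampus apart from GFP-negative cells of the same tissue, and log2 differences are GFP-positive minus GFP-negative. Astrocyte genes were higher in the GFP-positive cells, 18 of 20 measured members with 0 lower, at a median log2 difference of 2.78. Aqp4, the water channel of astrocytes, had a value of 10.91 ± 0.14 (SD, n = 3) in GFP-positive and 7.09 ± 1.03 (SD, n = 3) in GFP-negative cells, a 14.1-fold difference (limma, adjusted p = 3.52e-05). Microglia genes were lower, 15 of 16 members with a median of -3.29, and Csf1r, a receptor that microglia need to survive, had 6.40 ± 0.72 (SD, n = 3) against 10.82 ± 0.26 (SD, n = 3), 21.4-fold lower (limma, adjusted p = 2.19e-06). Genes of mature oligodendrocytes (14 of 15 lower, median -2.53) and of endothelium (12 of 13 lower, median -2.20) were lower as well.

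Over all genes tested by limma, 3390 of 19965 differed at a Benjamini-Hochberg adjusted p under 0.05, 1533 higher and 1857 lower in the GFP-positive cells. Of these, 599 of the higher and 948 of the lower genes differed at least 2-fold. At an unadjusted p under 0.05 there were 6061 genes, where chance gives 998. The values of both groups did not overlap for 38.9% of genes, where chance gives 10%. Both chance values are averages, and since genes vary together a random grouping can lie far from them. When both replicate 1 samples of the young mice, which had high choroid plexus genes, were left out, a setting added after these values were seen, 1841 genes passed, 1800 of them shared with the 3390. The balance of directions depended on the method: a SAM-type permutation test at the same false discovery rate called 6554 genes, 4291 higher and 2263 lower, and weighting the arrays gave 5736, 3035 higher and 2701 lower. Testing all 31672 probe sets gave 5242 probe sets, which is not a count of genes.

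**Figure D1:**
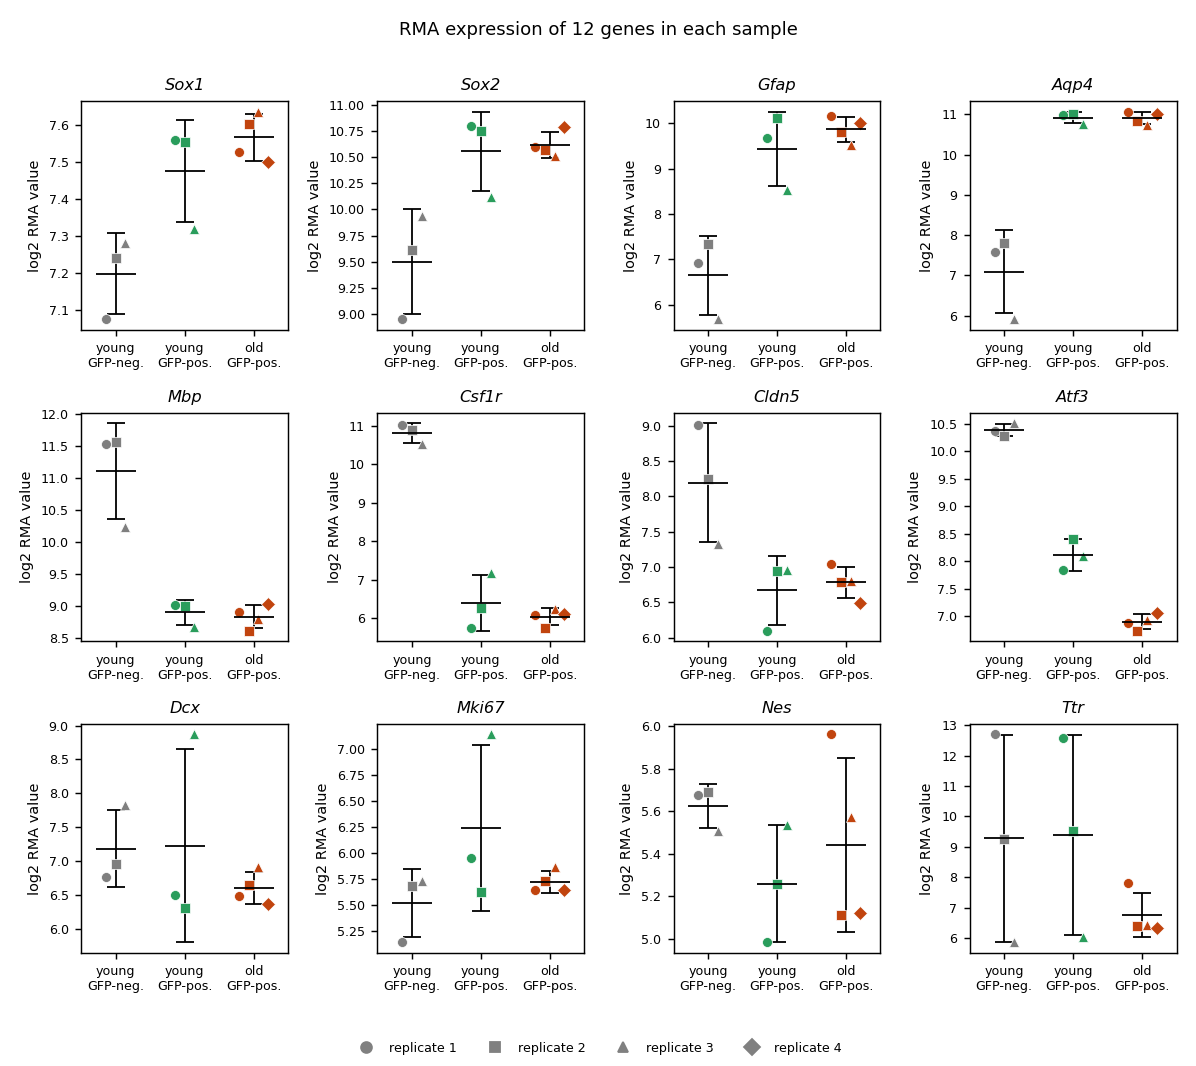
Log2 RMA value (vertical axis) of 12 genes in each of the 10 samples. Points are samples, with the shape giving the replicate number, and bars give the mean ± SD of young GFP-negative (n = 3), young GFP-positive (n = 3) and old GFP-positive (n = 4) cells. Aqp4 averaged 10.91 in young GFP-positive and 7.09 in GFP-negative cells, Atf3 averaged 8.11 in young and 6.90 in old GFP-positive cells, and Dcx reached 8.87 in the GFP-positive sample of the 4-month-old mouse.

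Among genes past the test whose groups did not overlap, the 6 largest positive differences were those of Nat8f5 (4.91 ± 0.22, SE, 30.0-fold), Atp13a4 (3.94), Slc39a12 (3.92), Aqp4 (3.82), Papss2 (3.82) and Cyp4f15 (3.80), with adjusted p from 1.39e-07 to 3.52e-05 in limma. Atp13a4 is a P-type transport ATPase, Slc39a12 a zinc transporter and Papss2 a sulfate donor synthase. The 6 largest negative differences were those of Il1a (-5.51 ± 0.86, SE), which encodes an inflammatory cytokine, the beta-globin genes Hbb-bt (-4.79) and Hbb-b2 (-4.79), the leukocyte surface gene Cd53 (-4.78), Arhgdib (-4.66) and Csf1r (-4.42). Il1a varied among the GFP-positive samples, from 4.24 to 8.66, and lay between 11.39 and 11.58 in the GFP-negative ones.

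Sox1 itself had a value of 7.48 ± 0.14 (SD, n = 3) in GFP-positive and 7.20 ± 0.11 (SD, n = 3) in GFP-negative cells. Its log2 difference of 0.28 ± 0.11 (SE) did not pass the test (limma, adjusted p = 0.123), although each GFP-positive value lay above each GFP-negative one, and passed with array weights (adjusted p = 0.0349). The related factor Sox2 was higher by 1.06 ± 0.24 (SE, adjusted p = 0.0111), a call lost without the choroid plexus-high samples (0.66, adjusted p = 0.112) and with age as a covariate (1.03, 0.0732). Also higher was Gfap, the intermediate filament of astrocytes and radial stem cells (2.80 ± 0.44, SE, adjusted p = 0.000979). Nes (-0.36, adjusted p = 0.287), the immature neuron gene Dcx (0.045, adjusted p = 0.964) and the proliferation gene Mki67 (0.72, adjusted p = 0.153) did not pass.

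Of the 24 lists, 17 were called by camera, 5 higher and 12 lower in GFP-positive cells. With an estimated correlation 4 calls held, those of microglia (adjusted p = 0.0454), mature oligodendrocyte (adjusted p = 0.0454) and antigen presentation (adjusted p = 0.0454), which were lower, and of growth factors and receptors (adjusted p = 0.0454), which was higher. Fry called 15 lists, 14 of them shared with the 17. Those it did not share were the mature neuron (adjusted p = 0.304), mural and fibroblast (0.127) and interferon lists (0.175). In the neural stem and progenitor list 13 of 23 members were higher and 1 lower, or 16 and 1 adjusted over the list alone, with a median of 0.85 (camera, adjusted p = 3.35e-06, and adjusted p = 0.0684 with an estimated correlation). Its leading members were Egfr (3.12 ± 0.12, SE), the epidermal growth factor receptor, Pax6 (3.01) and, in the other direction, Lpar1 (-3.24), a lysophosphatidic acid receptor that oligodendrocytes also express. The astrocyte list had 19 members higher adjusted over the list alone (camera, adjusted p = 2.08e-22, and adjusted p = 0.0684 with an estimated correlation), led by Ntsr2 (3.01), the amino acid transporter Slc7a10 (2.75) and the bicarbonate transporter Slc4a4 (3.18).

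Genes of growth factor reception and lipid synthesis were higher too. In the growth factor and receptor list 11 of 22 members were higher and 2 lower (13 and 2 adjusted over the list alone, median 0.77), among them Fgfr3 (2.77), also in the astrocyte list, and the hedgehog pathway factor Gli3 (2.97). Of the cholesterol synthesis enzymes and regulators, 14 of 17 were higher and 0 lower (16 higher adjusted over the list alone, median 0.90, adjusted p = 0.0939 with an estimated correlation), such as Sqle (1.17) and Mvd (0.99). The Notch list had 6 of 18 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.203 with an estimated correlation), led by Notch2 (1.83), the Notch-modifying enzyme Lfng (1.18) and the target Nrarp (1.41). The Wnt and BMP list was not called (camera, adjusted p = 0.326, and 0.0106 with all probe sets), with 4 of 20 higher and 2 lower (5 and 2 adjusted over the list alone). Among them were the BMP receptor Bmpr1b (3.48), Tcf7l2 (0.98) and the inhibitor Smad7 (-1.37).

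**Figure D2:**
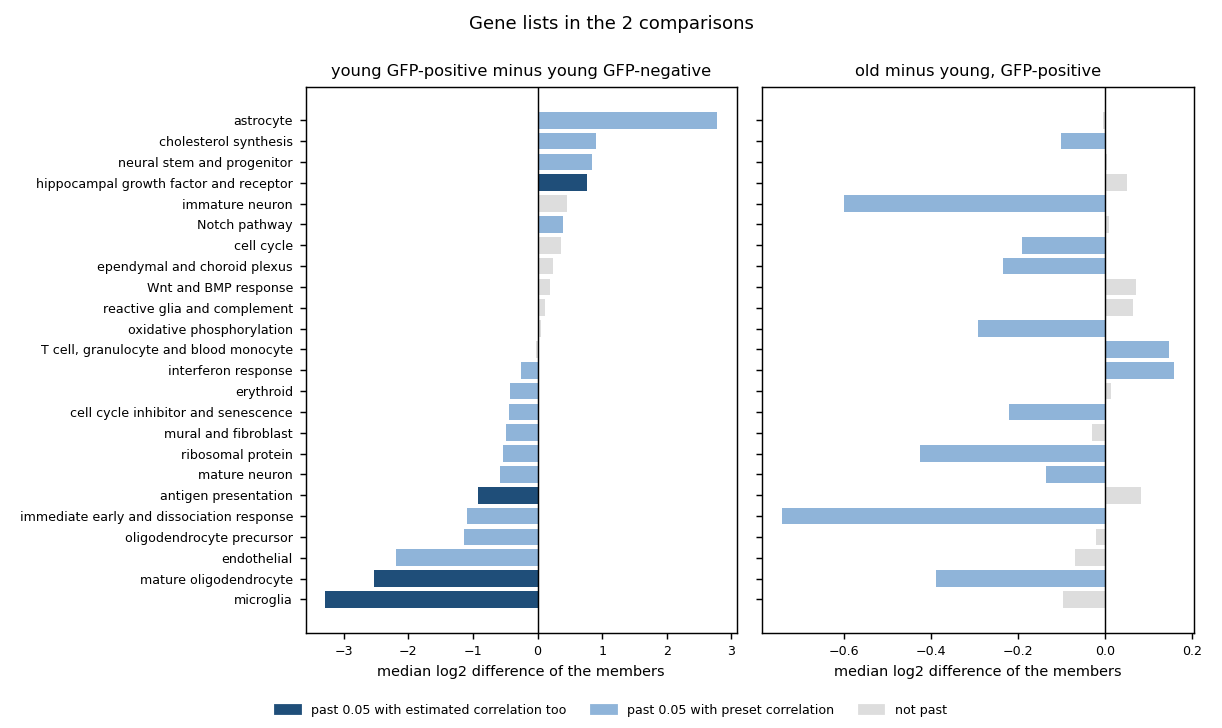
Median log2 difference of the members (horizontal axis) of the 24 gene lists for young GFP-positive minus young GFP-negative cells (left) and for old minus young GFP-positive cells (right), on separate scales. Dark bars mark lists past an adjusted p of 0.05 by camera with the preset and with an estimated correlation, light blue bars the preset alone, and grey bars neither. The left panel runs from -3.29 for microglia to 2.78 for astrocytes, and the right panel has 0 dark bars.

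Of the immune lists, those of microglia and antigen presentation were lower in GFP-positive cells. In the microglia list 15 members were lower adjusted over the list alone as well (camera, adjusted p = 3.35e-23), led by Ly86 (-4.17), the lectin gene Siglech (-3.04) and the purinergic receptor P2ry12 (-3.14). In the antigen presentation list 8 of 13 members were lower and 0 higher (10 lower adjusted over the list alone, median -0.92), with the class II genes Cd74 (-1.71) and H2-Aa (-1.82) and the class I gene H2-D1 (-1.04). The T cell, granulocyte and monocyte list was not called (camera, adjusted p = 0.326), and 2 of 14 members were lower, also adjusted over the list alone, the granulocyte genes S100a9 (-1.11) and S100a8 (-0.64, and -0.57 without the choroid plexus-high samples, then not past the test, adjusted p = 0.109). The reactive glia and complement list was not called (camera, adjusted p = 0.212), with a median of 0.12 but a mean of -0.38, and camera's direction was that of the mean. Fry called it lower (adjusted p = 0.00279). Of its 14 members 2 were higher and 4 lower (3 and 5 adjusted over the list alone), among them Cd14 (-3.41) and Cp (-2.42), both lower, and the cytokine receptor gene Osmr (1.16, adjusted p = 0.0239). The call of Osmr was lost when young GFP-negative replicate 2 or 3 (adjusted p = 0.0610 and 0.0739) or young GFP-positive replicate 2 or 3 (adjusted p = 0.0863 and 0.0538) was left out. Without both 4-month-old samples it was lost as well (0.97, limma adjusted p = 0.126).

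The oligodendrocyte lists and the endothelial list were lower as well, the precursor and endothelial ones in camera only with the preset correlation. The mature oligodendrocyte list (14 lower adjusted over the list alone; camera, adjusted p = 1.41e-18) was led by the myelin genes Cldn11 (-2.53), Mag (-3.54) and Cnp (-2.47). Of the oligodendrocyte precursor list, 11 of 12 members were lower and 0 higher (11 and 1 adjusted over the list alone, median -1.14, adjusted p = 0.115 with an estimated correlation), with the lineage factors Olig1 (-1.53) and Sox10 (-1.25) and the growth factor receptor Pdgfra (-3.79). The endothelial list (12 lower adjusted over the list alone, adjusted p = 0.144 with an estimated correlation) was led by the transporter gene Slco1a4 (8.01-fold lower), Ly6c1 (-3.46) and Ly6a (-2.66). The mural and fibroblast list had 5 of 13 lower and 1 higher (7 and 1 adjusted over the list alone, median -0.49, adjusted p = 0.428 with an estimated correlation), with Rgs5 (-1.87) and Acta2 (-1.82) lower and Pdgfrb (0.90) higher. Without the choroid plexus-high samples the calls of this list (median -0.28, adjusted p = 0.0653), Rgs5 (-1.24, 0.0562) and Acta2 (-1.32, 0.0980) were lost. The list also lost its call with age as a covariate (0.0503), as did Acta2, and without the dimmest 33.3% or 50% of genes (0.137 and 0.301). Of 5 measured erythroid genes the 2 globin genes were lower, also adjusted over the list alone (median -0.42, mean -1.99, adjusted p = 0.240 with an estimated correlation), and Alas2 had -0.42 (adjusted p = 0.163). Without young GFP-positive replicate 2 the erythroid median was -0.27. Without the dimmest 50% of genes the erythroid list was not called (adjusted p = 0.0606).

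Neuronal and cell cycle genes were mixed. The immature neuron list was not called (camera, adjusted p = 0.315, median 0.46), but 3 of 15 members were higher, also adjusted over the list alone: the intermediate progenitor gene Eomes (1.34, adjusted p = 0.00710), Cd24a (1.78, adjusted p = 0.00728) and Neurog2 (0.68, adjusted p = 0.0250). The mature neuron list had a median of -0.59 (camera, adjusted p = 0.0396, and adjusted p = 0.493 with an estimated correlation), with 3 of 18 lower and 2 higher (6 and 3 adjusted over the list alone). Nefm (-2.10) and the vesicular glutamate transporter Slc17a7 (-1.52) were lower, and Gad2 (1.89), which makes the transmitter GABA, was higher. The cell cycle list was not called (camera, adjusted p = 0.224), with 2 of 27 higher, Ccnd2 (0.92) and Ccnb2 (0.52), and 1 lower, Ccnd1 (-1.43), as adjusted over the list alone. Of the cell cycle inhibitor and senescence list 4 of 12 were lower and 0 higher, also adjusted over the list alone (median -0.43, adjusted p = 0.0939 with an estimated correlation), among them Cdkn1a (-2.29) and Gadd45b (-1.30). Without the dimmest 33.3% of genes this list was not called (-0.43, adjusted p = 0.0777).

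Single samples decided several of these neuronal calls. The mature neuron list was no longer called without young GFP-negative replicate 1 (median -0.26, adjusted p = 0.223), young GFP-negative replicate 2 (-0.47, 0.130) or young GFP-positive replicate 2 (-0.39, 0.169). Without young GFP-negative replicate 3 its call held, with a median of -1.003. By limma, Neurog2 lost its call without young GFP-negative replicate 1 or 2 (adjusted p = 0.0929 and 0.0690) or young GFP-positive replicate 3 (adjusted p = 0.0644). Gad2 lost it without young GFP-positive replicate 1 or young GFP-negative replicate 2 (adjusted p = 0.0630 and 0.0582), and Slc17a7 without either of these or young GFP-negative replicate 1 (adjusted p = 0.0680, 0.0883 and 0.0792). Ccnb2 lost it without young GFP-positive replicate 1 or 3 (adjusted p = 0.0996 and 0.0611) or young GFP-negative replicate 1 or 2 (adjusted p = 0.0944 and 0.0582). Other settings ended limma calls too. With only the 2 groups compared these were Neurog2 (adjusted p = 0.0559) and Slc17a7 (0.0731), and without the 4-month-old mice Neurog2 (0.0624), Gad2 (0.0598) and Ccnb2 (0.069). With age as a covariate they were Neurog2 (0.0739), Slc17a7 (0.0745) and Ccnb2 (0.0630). Other calls appeared: without young GFP-positive replicate 2 the immature neuron list (0.83, adjusted p = 0.0392), the cell cycle list (0.45, 0.0392) and Mki67 (1.02, 0.0482), and without young GFP-positive replicate 1 the cell cycle list (0.42, 0.0300). Leaving out the choroid plexus-high samples ended the calls of the mature neuron list (median -0.33, adjusted p = 0.0745), Slc17a7 (-1.03, 0.182), Ccnb2 (0.36, 0.263), Gad2 (1.47, 0.127), Nefm (-1.86, 0.0763) and Neurog2 (0.69, 0.117). The differences of Nefm and Neurog2 were about as large as over all samples, and with fewer samples there was less to test. The call of the mature neuron list was also lost without the dimmest 33.3% or 50% of genes (adjusted p = 0.239 and 0.438), with only the 2 groups compared (0.0647), with quantile normalization (0.0905) and with age as a covariate (0.107).

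Immediate early genes, which tissue dissociation also induces, were lower in GFP-positive cells, 8 of 16 members with 0 higher (13 lower adjusted over the list alone, median -1.09, camera adjusted p = 1.15e-08, and adjusted p = 0.155 with an estimated correlation). Atf3 (-2.28), a stress-induced transcription factor, Ier3 (-2.24) and Egr2 (-2.38) led the list. Ribosomal protein genes were lower, 22 of 62 with 0 higher (29 lower adjusted over the list alone, median -0.53, adjusted p = 0.144 with an estimated correlation), with Rps15a (1.99-fold lower), Rps27 (-0.85) and Rpl26 (-0.84, and -0.61, adjusted p = 0.0569, without the choroid plexus-high samples) in front. The interferon list had 0 of 16 members past the test, by limma over all genes or adjusted over the list alone, Ifi27 (-0.38, unadjusted p = 0.0123), Gbp3 (-0.67) and Ifitm3 (-1.63) coming closest. It had a median of -0.26 (camera, adjusted p = 0.0395, and adjusted p = 0.423 with an estimated correlation). That call was lost without young GFP-positive replicate 1 (-0.20, adjusted p = 0.0938) or 3 (-0.25, 0.0635) or young GFP-negative replicate 1 (-0.11, 0.244). It was also lost without the dimmest 33.3% or 50% of genes (adjusted p = 0.239 and 0.205), with array weights (0.105) or age as a covariate (0.0571), and without the choroid plexus-high samples (median 0.037, adjusted p = 0.473). Gbp3 passed limma's test without young GFP-positive replicate 2 or young GFP-negative replicate 3 (adjusted p = 0.0478 and 0.0214), and Ifitm3 without young GFP-positive replicate 2 (adjusted p = 0.0326). With array weights Ifi27 and Gbp3 passed (adjusted p = 0.0313 and 0.0364).

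Oxidative phosphorylation genes were not called as a list (camera, adjusted p = 0.824, median 0.048), with 3 of 85 members higher over all genes and 0 adjusted over the list alone. These were Ndufaf6 (0.97, adjusted p = 0.0195), Ndufs1 (0.41, adjusted p = 0.0451) and Cox7b2 (0.76, adjusted p = 0.0453) by limma. All 3 calls were lost without young GFP-negative replicate 1 (adjusted p = 0.0567, 0.104 and 0.145) or 2 (adjusted p = 0.0587, 0.103 and 0.131). Those of Ndufs1 and Cox7b2 were also lost without young GFP-positive replicate 1 (adjusted p = 0.124 and 0.147), where Ndufaf6 had 0.61, and that of Ndufs1 without young GFP-positive replicate 2 or young GFP-negative replicate 3 (adjusted p = 0.148 and 0.0924). With only the 2 groups compared all 3 were lost as well (adjusted p = 0.0555, 0.0546 and 0.0711), and without the choroid plexus-high samples too (0.0550, 0.224 and 0.336). The ependymal and choroid plexus list was not called either (camera, adjusted p = 0.326, median 0.25), with 0 of 12 members past the test in limma and Ccdc153 (0.66, adjusted p = 0.0562, unadjusted p = 0.0101) closest. The list was called without young GFP-negative replicate 1 (0.66, adjusted p = 0.0175), and Ccdc153 passed without young GFP-positive replicate 3 (adjusted p = 0.0377). Ccdc153 also passed without the dimmest 33.3% of genes (0.0462), with only the 2 groups compared (0.0372) and with array weights (0.00669). The choroid plexus genes of the list differed by sample: Ttr, the thyroid hormone carrier made in choroid plexus, had 12.59 and 12.69 in GFP-positive and GFP-negative replicate 1, 9.53 and 9.26 in replicate 2, and 6.03 and 5.88 in replicate 3.

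The age comparison asked how GFP-positive cells of old mice, 1 year and 9 months of age, differ from those of young mice, and log2 differences are old minus young. By limma 3 genes passed, all lower in old mice. They were Atf3 at 6.90 ± 0.14 (SD, n = 4) against 8.11 ± 0.29 (SD, n = 3), a log2 difference of -1.21 ± 0.14 (SE, adjusted p = 0.0368), and Svbp and Prmt1. Svbp, whose product is a partner of the tubulin-modifying vasohibins, fell (-0.99 ± 0.12, SE, adjusted p = 0.0368), as did the arginine methyltransferase gene Prmt1 (-0.89 ± 0.11, SE, adjusted p = 0.0440). Genes of protein synthesis and respiration lay lower in old mice as lists, with 50 of 62 ribosomal protein genes (median -0.42) and 74 of 85 oxidative phosphorylation genes (median -0.29) below 0, and so did all 16 immediate early genes (median -0.74). These list calls rested on the preset correlation between genes. Astrocyte and neural stem genes had medians of -0.0045 and 0.0032.

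No gene passed in the other direction over all samples and genes (0 higher by limma, where 938 had an unadjusted p under 0.05), while the SAM-type test called 4 genes, Adam23, Lgi1 and Lrrc9 higher and Svbp lower, Lgi1 being named after its values were seen. The smallest p among higher genes belonged to the adhesion gene Adam23 (1.28 ± 0.18, SE, adjusted p = 0.0760), Kctd14 (1.17, adjusted p = 0.0844) and Lrrc9 (1.29, adjusted p = 0.0844) in limma. They passed limma's test in some settings: without the dimmest 50% of genes (adjusted p = 0.0379, 0.0482 and 0.0499), Adam23 and Kctd14 with array weights (0.0357 each), and Kctd14 and Lrrc9 with the mean of probe sets (0.0324 and 0.0460). In all, 2028 of 19965 genes had an unadjusted p under 0.05, where chance gives 998 on average, and 10.9% did not overlap between the groups, where chance gives 5.71% on average. Genes vary together, so with so few samples a random grouping can lie far from these averages. Leaving out 1 sample ended the 3 calls in nearly every case, while the log2 differences without 1 sample stayed between -1.35 and -1.06 for Atf3, -1.04 and -0.95 for Svbp, and -0.94 and -0.81 for Prmt1. Svbp and Prmt1 lost theirs whichever 1 of the 7 GFP-positive samples was left out, and so did Atf3 except when it was young GFP-positive replicate 1. All 3 genes shared an adjusted p of 0.0972, 0.150, 0.0528 and 0.0530 without old replicates 1 to 4, 0.102 without young GFP-positive replicate 2 and 0.0886 without young GFP-positive replicate 3. Without young GFP-positive replicate 1 the values of Svbp and Prmt1 were 0.0610 and 0.0844. The number of genes past limma's test was 0 without old replicate 1, old replicate 2, young GFP-positive replicate 2 or young GFP-positive replicate 3 (1816, 1716, 1601 and 1953 at an unadjusted p under 0.05). It was 2 without old replicate 3 (4833420G17Rik and Hs3st3a1) and 2 without old replicate 4 (Olfr800 and Prim1), genes named after their values were seen and none of them shared with the 3, and 9 without young GFP-positive replicate 1, of which only Atf3 was shared. Among these 9 were Mag (-1.30), Ier2 (-2.06) and Rps26 (-1.13). The 3 calls were also lost with only the 2 groups compared (adjusted p = 0.0938 for Atf3 and Svbp and 0.153 for Prmt1), with quantile normalization (0.0640 each) and with the trend and robust prior (0.0776 each).

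Of the genes named in advance, Sox1 differed by 0.091 (adjusted p = 0.750), Sox2 by 0.06 (adjusted p = 0.928), Nes by 0.18 (adjusted p = 0.744) and Gfap by 0.43 (adjusted p = 0.702) in limma, none past the test. Dcx had 6.60 ± 0.24 (SD, n = 4) in old and 7.23 ± 1.43 (SD, n = 3) in young mice (limma, adjusted p = 0.661), and Mki67 5.72 ± 0.11 against 6.24 ± 0.80 (adjusted p = 0.557). Much of the young spread came from the 4-month-old mouse, at 8.87 for Dcx and 7.14 for Mki67, where the other young GFP-positive samples averaged 6.41 and 5.79.

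Camera called 12 of the 24 lists, 2 higher and 10 lower in old mice. With an estimated correlation 0 lists were called (3 at an unadjusted p under 0.05), and fry called 0 (4 at an unadjusted p under 0.05). In the ribosomal protein list 0 of 62 members passed over all genes and 26 were lower adjusted over the list alone, such as Rps26 (-0.96), Rps15a (-0.81) and Rpl30 (-0.67). Their adjusted p over all genes ran from 0.0844 to 0.147. The list had a camera adjusted p of 1.40e-19, and adjusted p = 0.204 with an estimated correlation. In the oxidative phosphorylation list 0 of 85 passed over all genes and 1 was lower adjusted over the list alone, with Atp5mpl (-0.62), Ndufs4 (-0.49) and Atp5d (-0.47) having the smallest p. Its camera adjusted p was 7.39e-20, and adjusted p = 0.337 with an estimated correlation. In the immediate early list 1 of 16, Atf3, was lower over all genes and 2 were lower adjusted over the list alone (camera, adjusted p = 5.87e-12, and adjusted p = 0.325 with an estimated correlation). Ier2 had -1.55 (adjusted p = 0.213) and Ier3 -0.66 (adjusted p = 0.381). Without young GFP-positive replicate 2 the median of the immediate early list was -0.29 (adjusted p = 1.90e-06).

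**Figure D3:**
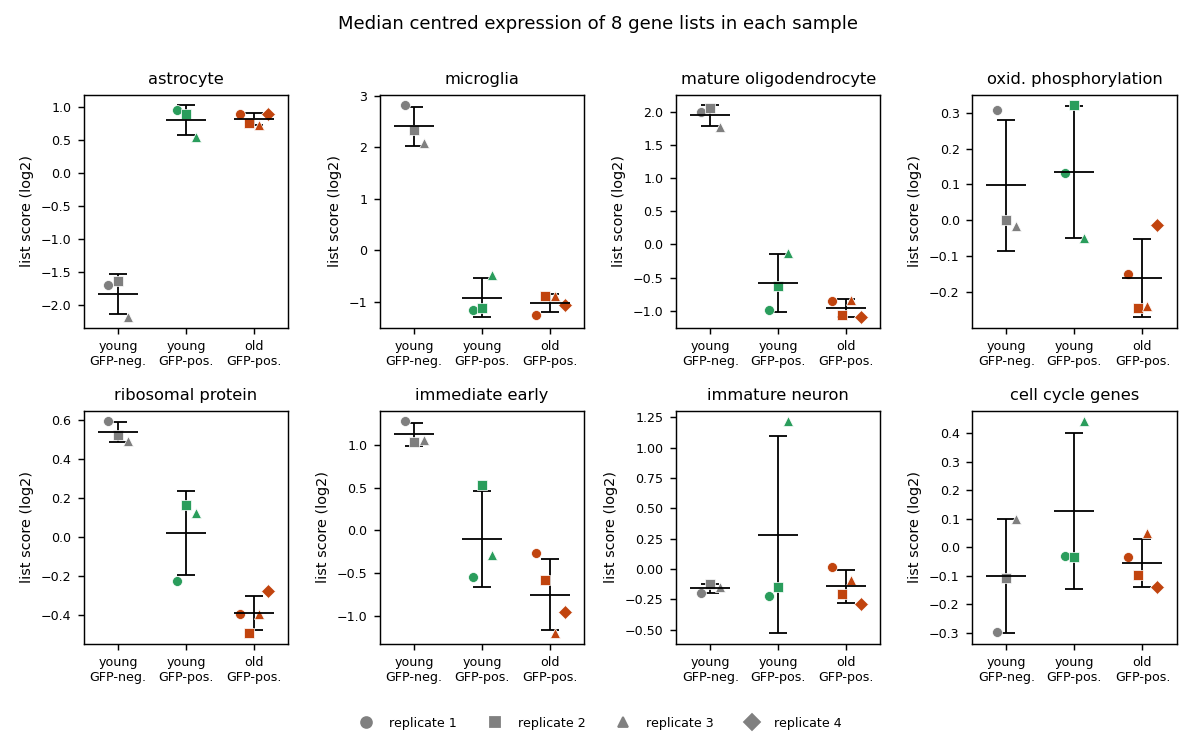
List score (vertical axis, the median over a list's genes of the log2 value minus that gene's mean over all samples) of 8 gene lists in each of the 10 samples. Points are samples, with the shape giving the replicate number, and bars give the mean ± SD of young GFP-negative (n = 3), young GFP-positive (n = 3) and old GFP-positive (n = 4) cells. The immature neuron score was 1.22 in the GFP-positive sample of the 4-month-old mouse and at most 0.021 in the other 9.

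Neurogenic and cell cycle genes lay lower in old mice, and much of this difference came from the 4-month-old mouse. All 15 immature neuron genes were below 0 (median -0.60, camera, adjusted p = 5.23e-07, and adjusted p = 0.400 with an estimated correlation), with 0 past limma's test over all genes or adjusted over the list alone. Its members Cd24a (-1.18), Eomes (-0.82) and Dpysl3 (-0.86) had unadjusted p from 0.00691 to 0.0193. Of the cell cycle genes 25 of 27 were below 0 (median -0.19, camera, adjusted p = 4.80e-06, and adjusted p = 0.554 with an estimated correlation), with 1 lower adjusted over the list alone, and Pcna (-0.81), Mcm4 (-0.55) and Ccna2 (-0.68) in front. Without young GFP-positive replicate 3, the sample of the 4-month-old mouse, the medians were -0.14 (adjusted p = 0.0514) and 0.013 (adjusted p = 0.311), and neither list was called. When the GFP-negative sample of 4 months was left out as well, the immature neuron list kept its camera call. The cell cycle list lost its call in that setting too (0.013, adjusted p = 0.300). Without young GFP-positive replicate 1 they were -0.97 and -0.35, and the immature neuron median was -0.91 without young GFP-positive replicate 2. The mature oligodendrocyte list followed the same sample, at -0.39 over all samples (camera, adjusted p = 0.00134, and adjusted p = 0.554 with an estimated correlation) and -0.18 without it (adjusted p = 0.106), and at -0.69 without young GFP-positive replicate 1. Its members Mag (-0.97), Mog (-0.73) and Cnp (-0.52) were the 3 lower when adjusted over the list alone. Without the dimmest 50% of genes neither the mature oligodendrocyte list (adjusted p = 0.102) nor the cell cycle list (0.230) was called.

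Smaller list differences had medians within 0.25 of 0. The cell cycle inhibitor and senescence list lay lower (median -0.22, camera, adjusted p = 0.00321, and adjusted p = 0.204 with an estimated correlation), with Trp53 (-0.62), Btg2 (-1.11) and Gadd45b (-0.50) in front, and its median was -0.14 without young GFP-positive replicate 1. Without the dimmest 50% of genes it was not called (adjusted p = 0.102). All 17 cholesterol synthesis genes were below 0 (median -0.10, camera, adjusted p = 0.00134, and adjusted p = 0.554 with an estimated correlation), led by Sqle (-0.32), Fdps (-0.47) and Dhcr7 (-0.45). The median was 0.0099 and no longer called without old replicate 3 (adjusted p = 0.142), the sample with high Xist. The call was also lost with quantile normalization (median -0.022, adjusted p = 0.0639) and without the dimmest 50% of genes (-0.10, 0.142). The median was -0.17 and -0.23 without young GFP-positive replicates 1 and 3. The interferon list lay higher (median 0.16, camera, adjusted p = 0.0381, and adjusted p = 0.669 with an estimated correlation), with 1 member higher adjusted over the list alone, Ifit3 (1.23, adjusted p over all genes = 0.263). Next came Oas1a (0.25) and Irf7 (0.34). It lost its call without old replicate 1, 2, 3 or 4 (adjusted p = 0.0604, 0.0649, 0.0706 and 0.0518) and without young GFP-positive replicate 1 or 3 (adjusted p = 0.236 and 0.0921). Nor was it called without the dimmest 50% of genes (adjusted p = 0.259), with quantile normalization (0.0528), the mean of probe sets (0.0549), all probe sets (0.316) or array weights (0.0752), or without the 4-month-old mice (0.0765) or the choroid plexus-high samples (0.183).

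Lists of other cells moved little. The T cell, granulocyte and monocyte list lay higher (median 0.15, camera, adjusted p = 0.0192, and adjusted p = 0.669 with an estimated correlation), with Nkg7 (0.30), Ccr2 (0.25) and Cd79a (0.28) in front. It lost its call without old replicate 3 (adjusted p = 0.0593) or young GFP-positive replicate 1 or 2 (adjusted p = 0.0720 and 0.0520). The call was also lost without the dimmest 33.3% or 50% of genes (adjusted p = 0.159 and 0.549), with quantile normalization (0.0671) and without the choroid plexus-high samples (0.0612). Over all genes the median difference was 0.053, and -0.034 without the dimmest 50% of genes, so dim genes in general lay higher in old samples. Ccr2 and Cd79a were dim, with means of 4.33 and 4.27 in old samples. The mature neuron list lay lower (median -0.14, camera, adjusted p = 0.0192, and adjusted p = 0.669 with an estimated correlation), with Rab3a (-0.70), Thy1 (-0.61) and Grin1 (-0.47) in front. It lost its call without old replicate 1 or 3 (adjusted p = 0.0711 and 0.0593) or young GFP-positive replicate 1 or 3 (adjusted p = 0.236 and 0.0921), with medians of -0.09, -0.15, -0.17 and -0.15. It also lost it without the dimmest 33.3% or 50% of genes (adjusted p = 0.159 and 0.293), with quantile normalization (0.0528) or array weights (0.119), and without the choroid plexus-high samples (0.114). Its median was -0.29 without old replicate 2 and -0.34 without young GFP-positive replicate 2. The ependymal and choroid plexus list lay lower (median -0.24, camera, adjusted p = 0.0365, and adjusted p = 0.669 with an estimated correlation), with Ttr at -2.63 ± 1.56 (SE), Tekt1 at -0.28 and Otx2 at -0.81, none past limma's test. Its median was -0.025 (adjusted p = 0.532) without young GFP-positive replicate 1, the sample with the highest Ttr among the GFP-positive ones. Its call was also lost without old replicate 2, 3 or 4 (adjusted p = 0.123, 0.0706 and 0.166) or young GFP-positive replicate 2 (adjusted p = 0.153), and its median was -0.38 without old replicate 1 and -0.40 without young GFP-positive replicate 3. Further losses came without the dimmest 33.3% or 50% of genes (adjusted p = 0.327 and 0.925), with quantile normalization (0.0528), with array medians set equal (0.0507) and with all probe sets (0.0634).

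The other 12 lists were not called between old and young mice, but single samples decided this for some. Without young GFP-positive replicate 3 the astrocyte list was lower in old mice (-0.11, camera, adjusted p = 0.00919). Without all samples of 4-month-old mice the astrocyte list (-0.11, adjusted p = 0.00475) and the neural stem list (-0.0825, adjusted p = 0.0458) were called lower. Microglia genes were called lower without young GFP-positive replicate 1 (-0.20, adjusted p = 0.00314) or 2 (-0.17, 0.0459), and endothelial genes without old replicate 1 (-0.079, 0.0317) or young GFP-positive replicate 1 (-0.27, 0.00240). Endothelial genes were also called lower with array weights (-0.14, adjusted p = 0.0397) and with only the 2 groups compared (-0.07, 0.0257). The camera adjusted p was 0.578 for neural stem and progenitor genes (mean -0.015, where Tnc, -0.48, had the smallest p), 0.507 for astrocyte genes (Slc7a10, -0.29) and 0.185 for microglia genes (median -0.10). It was 0.0577 for endothelial (median -0.07), 0.578 for mural and fibroblast (median -0.031), 0.578 for oligodendrocyte precursor (median -0.022) and 0.988 for erythroid genes (median 0.014, mean -0.17, camera's direction being higher). Notch pathway (median 0.0087), Wnt and BMP (median 0.07), growth factor and receptor (median 0.05) and antigen presentation genes (median 0.082) had camera adjusted p of 0.906, 0.966, 0.721 and 0.552. The reactive glia and complement list had a median of 0.063 and a mean of -0.017 (camera, adjusted p = 0.966). Of its members 8 lay above 0 and 6 below. It had 1 member higher and 1 lower adjusted over the list alone, and Serpina3n, a marker of reactive astrocytes, had -1.52 (limma, adjusted p over all genes = 0.299). The complement gene C4b, named after its values were seen, lay the other way, at 8.81 ± 0.33 (SD, n = 4) in old and 7.92 ± 0.33 (SD, n = 3) in young samples. Camera compares a list with all other genes, so its direction need not match the list's mean or median. That direction was lower for the reactive glia, neural stem and Notch lists, although the Notch mean (0.0052) and median were positive.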

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

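The splits of the samples for the sort comparison, the test of GFP-negative cells for the oxidative phosphorylation genes and the test on the sample of the 4-month-old mouse were chosen only after the results were seen.

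Among the 4 old samples, 4 of 151 values tested lay far from the other 3 by Dixon's criterion, which chance meets about 1 in 20 times, or 7.55 times here. These were C1ql1 in old replicate 1 (5.92, others 6.13 to 6.16), Slc7a10 in old replicate 2 (9.50, others 9.65 to 9.66), Ttr in old replicate 1 (7.83, others 6.35 to 6.44) and the score of the cell cycle inhibitor and senescence list in old replicate 4 (-0.43, others -0.27 to -0.25). Of the 7082 probe sets without a gene symbol, which no comparison used, 456 were higher and 398 lower in GFP-positive than in GFP-negative samples when tested with all probe sets, and 3 differed between old and young mice.

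Splits of the same samples into groups of the same sizes show what other groupings give. For GFP-positive against GFP-negative cells there are 10 splits, too few for a share under 0.05. The real split gave 3390 genes and the highest other 1 gene, so that 1 of 10 splits gave as many. Every other split put GFP-positive and GFP-negative arrays in both groups. The sort difference then entered the spread within groups and held the gene calls down, so these gene counts say little about chance. For lists the real split gave 17 and the highest other 17, and 2 of 10 splits gave as many. For old against young mice chance cannot be excluded. Here 2 of 35 splits gave at least the 3 genes of the real split, the highest other giving 4 (old replicate 3 with the 3 young samples against the other old samples). For lists 2 of 35 gave as many as 12 lists, the highest other giving 12. The other splits called between 2 and 12 lists by age, and between 8 and 17 by sort. The number of lists called by camera at the preset correlation therefore does not set the real groupings apart.

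Ribosomal protein and oxidative phosphorylation genes were lower in old samples by medians of -0.42 and -0.29. The oxidative phosphorylation scores of the groups overlapped, with -0.012 in old replicate 4 and -0.048 in young GFP-positive replicate 3. A weaker response of bright genes on the old arrays would lower any genes of like brightness. In 10000 random lists matched for brightness, however, the lowest median was -0.18 against the ribosomal and -0.17 against the oxidative phosphorylation list. This puts both lists at percentile 0. Random lists hold unrelated genes, while the members of these 2 lists varied together (estimated correlations of 0.22 and 0.36). The percentile therefore concerns brightness alone, and does not exclude another shift shared by the members of a list. More GFP-negative cells in the young samples would raise microglia genes there by a log2 value of 2.20 for the ribosomal difference, at a share of 36.9%. The observed microglia difference, young minus old, was 0.12 ± 0.26 (SE), which argues against this for the ribosomal list. Even a share of 100%, with microglia genes raised by 3.34, would not supply the oxidative phosphorylation difference. Those genes were not higher in GFP-negative than in GFP-positive young cells (median 0.048, GFP-positive minus GFP-negative). The microglia genes therefore add nothing for that list. Differences in dissociation, in RNA quality or in the recovery of short transcripts, carry-over of oligodendrocytes alone, and age itself stay open and were not tested.

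Immediate early genes were lower in old samples by a median of -0.74, and were far higher in GFP-negative than in GFP-positive young cells. Single old and young samples overlapped. The list scores were -0.26, -0.58, -1.20 and -0.96 in old replicates 1 to 4, and -0.55, 0.54 and -0.29 in young GFP-positive replicates 1 to 3. Carry-over of GFP-negative cells into the young samples may lower the old values in comparison, and would need a share of 21.4%, with microglia genes raised by 1.65. The observed microglia difference of 0.12 ± 0.26 (SE) argues against carry-over of the GFP-negative mix as measured. Carry-over of oligodendrocytes alone, whose genes were lower in old samples (median -0.39), was not tested and stays open. A difference in handling or dissociation time between the old and the young samples was not tested and stays open beside age.

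Immature neuron and cell cycle genes were high in the GFP-positive sample of the 4-month-old mouse, where 18 of 42 members (42.9%, against 0.997% of all genes) exceeded the mean of the other young GFP-positive samples by a log2 value over 1. Of these 18 members, 15 lay above every GFP-negative sample, among them Neurod1 (7.59, at most 5.09 in GFP-negative samples) and Top2a (7.37, at most 5.83), more than a mix with cells of the measured GFP-negative profile would give. Markers of GFP-negative cells were higher in that sample too: the microglia list score was -0.49, against -1.17 and -1.12 in the other two young GFP-positive samples, and the mature oligodendrocyte score -0.13, against -0.99 and -0.63. GFP-negative cells, such as a subset rich in immature neuron or cell cycle transcripts, therefore remain a candidate source, since no sample measured such a subset. The age of that mouse, its dissection and the gate of the sort stay open as well.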

How the results depend on the processing

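Settings that left out samples with high choroid plexus genes or high Xist were chosen only after the values were seen. The causes of the changes below were not tested, except that settings with fewer samples or genes have less to test. For GFP-positive against GFP-negative cells the number of genes moved from 3390 to 5736 with array weights (52.9% higher, against 45.2%), 1841 without the choroid plexus-high samples and 6554 with the SAM-type test (65.5% higher), and lay between 2393 and 3600 without 1 sample. With all probe sets, which adds tests, 5242 probe sets rather than genes passed. The number of lists moved from 17 to 4 with an estimated correlation and lay between 16 and 18 without 1 sample. For old against young mice the 3 genes became 9 without the dimmest 50% of genes, 0 with only the 2 groups compared, 0 with quantile normalization, 5 with the mean of probe sets, and 0 with the trend and robust prior. With all probe sets 8 probe sets passed, 3 of them without a gene symbol. They became 20 with array weights, 1 without the 4-month-old mice, 5 without the choroid plexus-high samples, and 0 to 9 without 1 sample. By limma at an unadjusted p under 0.05, the settings with 0 genes had 1873, 2046 and 2100. The 12 lists became 4 without the dimmest 50% of genes, 7 with quantile normalization, 7 without the 4-month-old GFP-positive and the Xist-high samples together, 0 with an estimated correlation and 0 with fry (3 and 4 at an unadjusted p under 0.05), and 7 to 11 without 1 sample. With the replicate number as a block, 3285 genes and 17 lists were called by sort and 0 genes (3113 at an unadjusted p under 0.05) and 11 lists by age. The calls of Gad2 by sort (adjusted p = 0.0647) and of the interferon list (0.0506), Atf3, Svbp and Prmt1 (0.109 each) by age were absent under the block, and no other call of a list or named gene was. By the ages in the titles, young fractions with number 2 came from different mice, and so did old and young samples of any number. The block by age thus joined different mice. For young fractions with numbers 1 and 3 the titles do not say whether they share a mouse, and the number was not read as a pairing. Deviations from the group means correlated across genes, which are not independent replicates, between young fractions of the same number with r of 0.124, 0.0211 and 0.191, and between old and young GFP-positive samples with -0.0184, -0.0674 and 0.216. Young GFP-positive replicate 2 correlated better with GFP-negative replicate 1 (0.0780) than with its own number, while replicates 1 and 3 correlated best with theirs, and Ttr went with the number in both fractions.

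A few list medians reversed. These were interferon by sort without the choroid plexus-high samples (0.037), neural stem and progenitor by age without the 4-month-old mice (-0.0825, then called lower in old mice, adjusted p = 0.0458), cell cycle by age without the 4-month-old mice (0.013) or without young GFP-positive replicate 3 (0.013), and cholesterol synthesis by age without old replicate 3 (0.0099). The lists of oxidative phosphorylation, ribosomal protein and immediate early genes kept their camera call by age, at the preset correlation, in the settings of samples, genes and scaling, with medians from -0.43 to -0.22, -0.50 to -0.34 and -0.97 to -0.29. With an estimated correlation these 3 calls were lost (adjusted p = 0.337, 0.204 and 0.325), and fry called none of the 3. Without 1 sample, the median of the cell cycle list by age lay between -0.35 and 0.013 and that of cholesterol synthesis between -0.23 and 0.0099. Some values changed sign while called neither in the main fit nor in the alternative. They were 12 of all 1157 gene and 50 of all 480 list values by age, and 7 of 1584 and 18 of 456 by sort. These totals include called values, so the shares among uncalled values alone are larger. The arrays give no background level, so signal over background was not analysed here.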

Other observations

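The values in this part were looked at only after the data had been seen, and no explanation was tested for them. Choroid plexus genes were high in both young samples with number 1: Clic6 had 7.92 in GFP-positive and 7.92 in GFP-negative replicate 1 and 4.28 to 4.65 in the other 8 samples, and Kl had 7.37 and 8.27 against 4.75 to 5.33. The median of the choroid plexus genes was 7.66 and 7.73 in these samples and 5.57 to 6.05 in the other 8. In old replicate 3, the sample with a high Xist value, the Y-linked gene Eif2s3y had 3.47, and it had 8.30 to 9.05 in the other 9 samples.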
